A study of Mus musculus with 2 samples.

How the data were processed

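Polyadenylated RNA from the spleen of 1 male C57BL/6J mouse aged 10 weeks was sequenced from 2 libraries, labelled technical replicates 1 and 2 of 1 biological replicate. Per the labels, the second library dates from 2015 and did not enter an earlier publication of 2014, and both libraries were made for a size range of 350 to 450, with no unit given. The labels define no treatment or second tissue, so the comparison made here was technical replicate 2 over technical replicate 1.

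The authors deposited 1 gene table and 1 transcript table per library. Per the file headers and the text deposited with them, the reads were aligned to the transcriptome of mouse genome mm10 with GENCODE release M4. The aligner, the quantifier and their versions were not given in the sources used here. Per the file headers, the deposited tables hold an expected count per gene and transcript, in which reads shared between genes are divided among them. The deposited TPM values sum to 1000000 in each library. The deposited FPKM values were proportional to TPM within each library. In the transcript tables, per the file headers, the deposited percent value gives the share of a gene's TPM held by each transcript. Lengths and effective lengths in the deposited tables are an other measure, in bases. The median difference between length and effective length was 191.1 bases in replicate 1 and 134.6 bases in replicate 2.

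Each gene table has 69691 rows. Of these, 43346 carry an Ensembl gene identifier, and 42462 of those were matched to a symbol. Another 26248 rows carry a numeric identifier that was not matched to a gene, and 97 are spike-in rows, which held 0 counts. Rows without an Ensembl identifier stayed out of library sizes and tests, and held 1.09e-05% of the counts in replicate 1 and 2.10e-04% in replicate 2. GC content, coordinates and gene classes came from GENCODE release M21 on the same genome (GRCm38), and 101510 of 103639 transcripts were matched to it. GC content and length of a gene were averages over its matched transcripts, weighted by their mean TPM in the 2 libraries.

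Total expected counts on genes were 27528824 in replicate 1 and 3806381 in replicate 2. Expected counts were rounded to whole numbers. Genes were tested with a mean TPM of at least 1 and at least 50 counts over both libraries, which left 12467 genes. Library sizes were scaled with edgeR 4.0.16 (TMM) in R 4.3.3. The log2 ratio of each gene was given an exact Clopper-Pearson 95% interval, conditional on the gene's count in both libraries. A gene was called higher or lower when its whole interval lay beyond 1.5-fold. A count of 0 was set to a floor of 3 counts per library, which makes the ratio an approximate bound. Intervals and floors cover counting error only, since PCR duplicates are not independent molecules. With 1 library on each side there is no replicate check and no p-value, and every call compares these 2 libraries. The technical coefficient of variation came from the edgeR common dispersion with both libraries as 1 group.

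Gene lists were fixed before the data were examined. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean TPM, and separately, chosen after seeing the data, matched on TPM, GC content and length. The mean TPM comes from these same 2 libraries, so a gene far higher in either can enter a high stratum through its ratio. Percentiles are therefore descriptive and not independent of the ratios. The named genes were fixed by rule before the data were examined. They are the 20 nuclear-encoded genes with the highest mean TPM, the leading members of each list, and the 10 highest and 10 lowest ratios among called genes with a mean TPM of at least 5. Some genes that the rule names are not reported here. The dominant transcript was compared for genes with a mean TPM of at least 10, counts in both libraries and at least 2 transcripts.

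The calling rule was tested on simulated data, with Poisson counts drawn for the 12467 genes at the TMM-scaled library sizes and 200 genes changed. For the comparison of replicate 2 against 1, it called 30 of 50 genes at a simulated fold of 2, 50 of 50 at 4, 16 of 50 at 0.5 and 40 of 50 at 0.25. Among 12267 unchanged genes it called 3. Intervals held the simulated value for 95.65% of genes. Other scalings (DESeq2 1.42.0 size factors and total count), filters, thresholds, interval levels, pseudocounts and TPM estimates were run as alternatives. Removal of the GC and length trends was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.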

Results

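The data are gene and transcript quantifications from 2 RNA-seq libraries of 1 mouse spleen. Both are labelled technical replicates of the same biological replicate, so the comparison asks how closely a second library from the same organ returns the first. Replicate 1 held 27528824 expected counts on genes and replicate 2 held 3806381, a depth ratio of 7.23. At 1 TPM, 13937 genes were detected in replicate 1, 9390 in replicate 2 and 8993 in both. Of the rest, 4944 reached 1 TPM in replicate 1 alone and 397 in replicate 2 alone.

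Both libraries carried the transcripts of spleen cell types. All 18 B cell genes reached 1 TPM in each library, as did 17 of 18 red pulp macrophage genes in replicate 2 and 18 in replicate 1. Their levels differed widely, and among the lists the erythroid one had the largest absolute difference in summed TPM. The erythroid list summed to 43584 TPM in replicate 1 and 442903 TPM in replicate 2. Mitochondrially encoded genes summed to 106316 TPM and 4286 TPM. The 10 genes with the highest TPM held 19.6% of all TPM in replicate 1 and 55.4% in replicate 2, and 46 of the top 100 genes were shared.

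Of 12467 genes tested, 3492 were higher and 4060 lower in replicate 2, with the 95% counting interval beyond 1.5-fold. Together these were 60.6% of the tested genes, and 46.2% of the calls were higher. The direction of many calls rests on the scaling. TMM moved every log2 ratio up by 1.26 against total counts, and the median log2 ratio was -0.27 under TMM, -0.14 under DESeq2 size factors and -1.53 under total counts. As a TPM ratio with a pseudocount of 1, the median over tested genes was -2.10, so a list median below 0 on that measure can still lie above the typical gene. Under total counts 1820 genes were higher and 7295 lower, so that 19.97% of the calls were higher. Under TMM, DESeq2 and total count scaling with TPM moving the same way, 1470 genes were higher and 3804 lower. This joint criterion was chosen after seeing the data, and directions given below as holding under every scaling refer to it. Total counts lower every log2 ratio against TMM, so they can remove higher calls but no lower ones. The 3804 lower genes are as many as under DESeq2 alone. A surplus of lower over higher genes by the joint criterion is therefore partly built in, also within lists. Other counts of list members are under TMM. Of 14 list medians above 0 under TMM, 10 were below 0 under total counts and 13 as a TPM ratio, while the 12 below 0 stayed below. Under total counts they could not do otherwise, so this is no sign that they are more stable.

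Pearson's r of log2(TPM + 1) was 0.708 and Spearman's rho 0.734, across 20511 genes above 0 in at least 1 library. Genes are not independent replicates. The technical coefficient of variation was 95.3%, taking the labels at their word that both libraries are technical replicates. Whether their reads were processed alike was not given in the sources used here. Chi-square over its degrees of freedom was 1062.5 (1 if the libraries differed by counting alone), and in 20 simulated pairs with Poisson counts at these depths at most 6 genes were called.

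Among erythroid genes, 11 of 19 were higher in replicate 2 and 3 lower. Hba-a1 and Hba-a2, the adult alpha globin genes, rose from 21651 to 195490 TPM and from 3077 to 217252 TPM. These 2 copies are near identical, so the split between them is uncertain. The beta globin genes Hbb-bs and Hbb-bt rose less, from 13808 to 17876 TPM and from 4015 to 11285 TPM. All 4 were higher under every scaling. The ratio of alpha to beta globin counts was 1.22 in replicate 1 and 11.6 in replicate 2. Erythroid genes without globin had 7 higher and 3 lower of 15, with a median of 0.87 at percentile 92.9. Among them Gata1 and Klf1, transcription factors of red cell development, were higher at 3.47 (3.04 to 3.89) and 3.05 (2.59 to 3.49) and Epor, the erythropoietin receptor, at 3.52 (2.79 to 4.22). Hemgn and Epb42, a membrane skeleton protein gene of red cells, were lower at log2 ratios of -2.18 (95% interval -3.06 to -1.43) and -2.37 (-3.38 to -1.53), and these 5 kept their direction under every scaling. With the GC trend removed, a step added after seeing the data, Gata1 was at 2.49, Klf1 at 0.13, Epor at 0.76, Hemgn at -1.02 and Epb42 at -1.16. The erythroid median of 1.39 stood at percentile 97.8 of matched random lists, and at 95.5, inside their central 95%, when these were matched also on GC and length, a match chosen after seeing the data. It was 0.13 under total counts and -0.97 as a TPM ratio.

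Heme and iron handling genes had 11 of 19 higher and 3 lower under TMM, at percentile 95.3, and 4 higher and 3 lower under every scaling. Their median of 1.22 was -0.05 under total counts and -1.28 as a TPM ratio. Ftl1, the ferritin light chain, rose at a log2 ratio of 4.05 (4.01 to 4.10), while Ncoa4, a receptor for ferritin breakdown, fell at -4.30 (-4.90 to -3.76) and the iron exporter Slc40a1 at -2.01 (-2.18 to -1.85). These 3 kept their direction under every scaling.

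Cytosolic ribosomal protein genes were higher for 69 of 81 members and lower for 4, with a median log2 ratio of 2.60 at percentile 100 of matched lists. Under every scaling 39 were higher and 2 lower, and the median was -0.03 as a TPM ratio. Rplp1 and Rplp2, proteins of the ribosomal stalk, rose from 238.5 to 35577 TPM and from 390.0 to 35749 TPM. Rps24 was 10080 and 6177 TPM, with a log2 ratio of 2.49 under TMM and a lower TPM in replicate 2. Within a library these genes spread widely, with an SD of log2 TPM of 1.98 in replicate 1 and 2.34 in replicate 2.

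Of 15 mitochondrially encoded genes tested, 10 were lower and 5 higher in replicate 2, with a median log2 ratio of -2.87 below all matched random lists (percentile 0). mt-Co1, a subunit of cytochrome oxidase, fell from 23002 to 157 TPM and mt-Cytb from 9341 to 103 TPM. mt-Atp6 and mt-Nd4l had 0 counts in replicate 2. In contrast mt-Co2 was 1254 and 1269 TPM and mt-Nd6 168.2 and 423.5 TPM. Those 2 were higher under every scaling, while mt-Co3, mt-Rnr1 and mt-Rnr2 were higher under TMM and lower in TPM. Nuclear copies of mitochondrial sequence on chromosome 1 share these reads, so the split between a mitochondrial gene and its copy is uncertain. The directions of single genes such as mt-Co2 and mt-Co3 are therefore uncertain too, also where they held under every scaling. Gm28661 (1: 24614885 to 24615565, GRCm38) had 227897 counts and 0, at least 4379-fold lower, and Gm28437 had 200317 and 2 counts, a log2 ratio of -12.50 (-15.54 to -10.64).

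**Figure D1:**
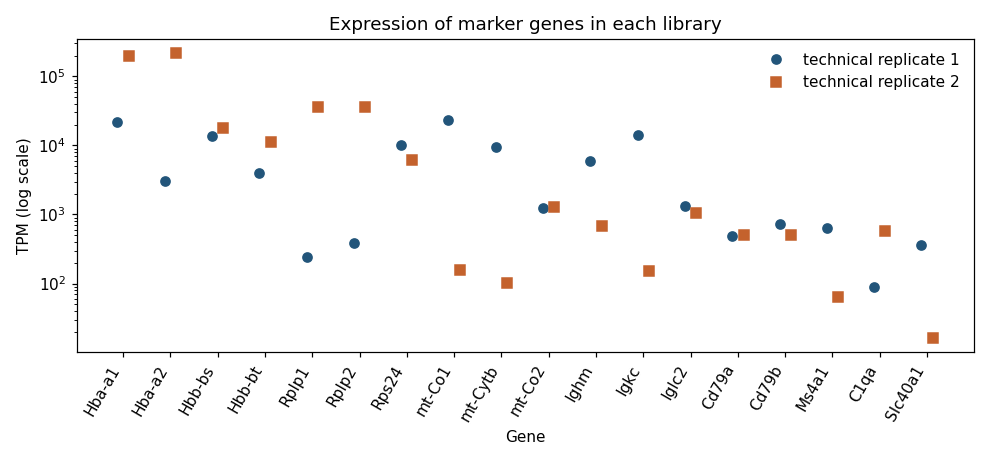
TPM (log scale) of 18 genes in technical replicate 1 (circles) and technical replicate 2 (squares), 1 library each. Alpha globins and Rplp1 sit far higher in replicate 2, and mt-Co1, mt-Cytb and Igkc far lower.

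B cell genes had 7 of 18 higher and 9 lower under TMM, with a median log2 ratio of -0.78 at percentile 2.44. Their matched random lists had a median of 0.57, against -0.27 over all tested genes. Under every scaling 3 were higher and 8 lower. The antigen receptor subunit Cd79a was 5.66-fold higher, and Cr2, Ms4a1 and Bank1 were lower at log2 ratios of -1.39, -0.91 and -3.22, all 4 under every scaling. With the GC trend removed, a step added after seeing the data, Cr2 was at 0.03 and Ms4a1 at 0.72. Bank1 at -1.99 and Cd79a at 1.52 kept their direction. Cd79b was higher under TMM at 1.94 but went from 737.7 to 499.4 TPM. T cell genes had 2 higher and 7 lower of 18 under TMM, and 0 higher and 6 lower under every scaling. Il7r, the interleukin 7 receptor, was lower at -3.12 (-3.63 to -2.65). NK and cytotoxic genes had 2 higher and 6 lower of 12 under TMM, and 0 higher and 5 lower under every scaling. Plasma cell genes had 5 higher and 1 lower of 10, with Mzb1 higher at 3.46 (3.34 to 3.58) and the other 4 higher genes under 5 mean TPM. Their summed TPM went from 1847 to 424.3, and their median of 0.60 was -0.64 over the 5 genes with a mean TPM of at least 10. The T cell, NK and plasma cell medians lay at percentiles 30.2, 23.4 and 78.2.

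Antigen receptor genes split between constant and variable parts. Immunoglobulin variable segments held 63980 counts over 216 genes in replicate 1 and 3 counts over 2 genes in replicate 2. The ratio was 1229-fold lower, with a 95% interval of 421 to 5961. The heavy, kappa and lambda variable lists had 57 of 71, 65 of 71 and 3 of 3 members lower and 0 higher. Their medians, with genes at 0 set to the bound, were -1.93, -2.57 and -3.80, at percentiles 0, 0 and 0.52. The summed constant genes had a log2 ratio of -0.25 (-0.27 to -0.22) under TMM and -1.51 under total counts, and went from 23492 to 2377 TPM. The variable segments stood at -10.26 and -11.53 under the same 2 scalings. Within the constant list 2 of 9 were higher and 3 lower at percentile 11.8, with Igkc falling at -3.64 (-3.87 to -3.42), Igha rising at 3.10 (146.0 to 226.7 TPM) and Ighm at -0.57. T cell receptor variable segments held 2524 and 6 counts, against 5073 and 444 in the constant genes, of which 1 was higher, 1 lower and 1 neither (percentile 47.0). Trac had 1028 counts and 0.

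Red pulp macrophage genes, of the cells that recycle red blood cells, had 6 of 18 higher and 6 lower under TMM. Under every scaling 2 were higher and 5 lower. C1qa was higher at 5.16 (5.07 to 5.26), and Adgre1 was lower at -1.99 (-2.42 to -1.60). Dendritic cell genes had 5 higher and 5 lower of 14 under TMM, and 2 higher and 5 lower under every scaling. Bst2 and Batf3 were higher and Clec9a and Itgax lower under every scaling. MHC class II genes had 5 higher and 3 lower of 10 under TMM but 1 higher and 3 lower under every scaling, and their median of 0.81 was -0.45 under total counts and -1.66 as a TPM ratio. Neutrophil genes had 4 higher and 3 lower of 13, and megakaryocyte and platelet genes 4 higher and 3 lower of 9. Stroma and endothelium had 9 higher and 6 lower of 19, with the chemokine Ccl19 higher at 4.22 and Cxcl13 lower at -2.81. The medians of these 6 lists lay at percentiles 18.3, 61.1, 59.9, 68.4, 85.9 and 63.2, in the order named.

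Genes of neighbouring organs were low in both libraries. Pancreatic genes summed to 97.1 TPM in replicate 1 and 4.60 TPM in replicate 2, with 4 of 9 lower and 0 higher at percentile 12.4. Adipose and mesothelial genes had 5 of 7 higher at percentile 99.1, but their median was -0.36 as a TPM ratio. Liver genes summed to 5.59 and 11.7 TPM, with only Cyp2e1 tested. Among process lists, cell cycle genes had 8 of 18 higher and 5 lower under TMM but 1 higher and 4 lower under every scaling, with a median of 0.46 that was -0.80 under total counts. The same counts under TMM were, for immediate early genes, 6 of 15 higher and 1 lower, and for interferon response genes 2 of 15 higher and 5 lower. The percentiles of the 3 lists were 89.5, 91.9 and 19.6. Junb, an early response transcription factor, rose from 1.11 to 87.9 TPM. Replication-dependent histone genes had 4 of 6 higher at percentile 98.3, with a median of -0.81 as a TPM ratio. The sex check list had 2 of 4 lower at percentile 13.6, and Xist was at 0.03 and 0.38 TPM.

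**Figure D2:**
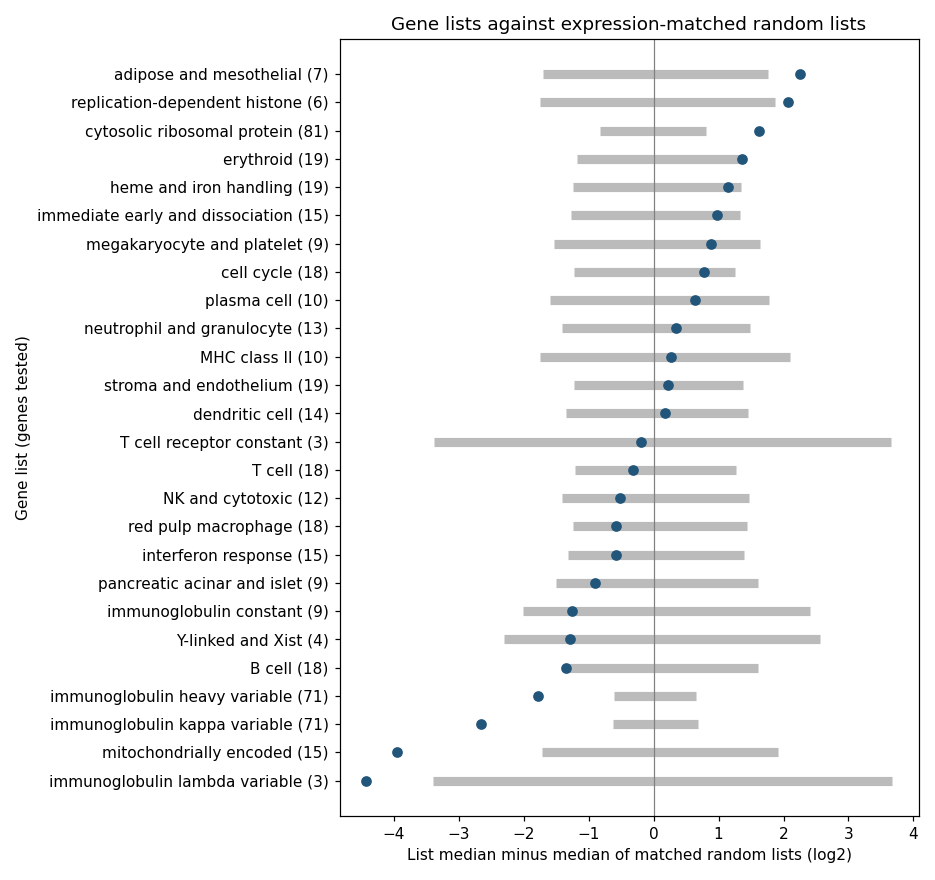
Median log2 ratio of each fixed gene list minus the median of its expression-matched random lists (points), with the central 95% of the random lists (grey bars) and the number of genes tested in parentheses. Cytosolic ribosomal protein, adipose, histone and erythroid genes lie above their range, and B cell and mitochondrially encoded genes and the immunoglobulin variable lists lie below theirs. Matching used the mean TPM of these same libraries.

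The highest ratios belonged to Scand1 (2: 156311847 to 156312704), with 0 counts in replicate 1 and 1997 in replicate 2, at least 11549-fold higher, followed by Ccdc85b, Gm26917, Rn7sk, Mir142hg, Il3ra, Plac9b, Rpl17-ps5, Hmga1b and Tpgs1. Rn7sk, a small nuclear RNA without a poly(A) tail, had 4 and 402 counts. The lowest ratios belonged to Gm28437, Gm28661, Gm1966, ENSMUSG00000100725.2, Smcr8, Erbin, Igkv1-117, Gm21092, Rcor1 and Crkl. Smcr8 had 3822 counts and 1, a log2 ratio of -7.78 (-13.09 to -5.30). All 20 kept their direction under every scaling. Beyond genes already named, the 20 nuclear genes with the highest mean TPM included Rps9, Rps21, Rpl13a and Rack1, higher under every scaling, and Eef1a1 and Gm10925, lower under every scaling. Tmsb4x was higher under TMM and lower in TPM, Tpt1 changed sign under total counts, and Gm29216 was not called.

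The ratio between the libraries followed the GC content and length of the transcripts. Over 10 bins of equal size, the bin with the lowest GC had a median log2 ratio of -1.65, with 70 genes higher and 776 lower. In the highest bin it was 2.54, with 909 higher and 45 lower. From the shortest to the longest bin it went from 1.53 to -1.58. Across genes, Spearman's rho of the ratio was 0.53 with GC and -0.39 with length. GC was known for 99.8% of tested genes. Because GC and length were weighted by transcript TPM in these same libraries, the trends are not fully independent of the ratio.

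**Figure D3:**
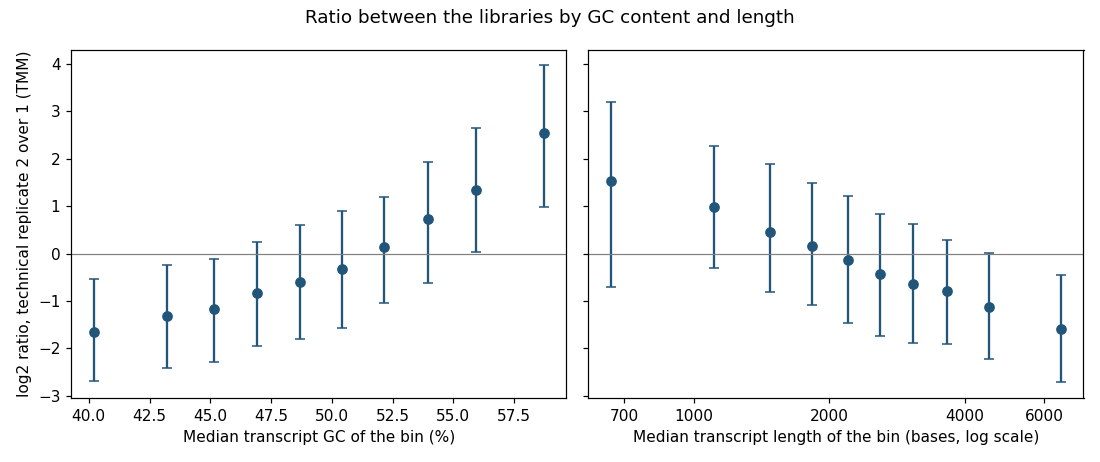
Log2 ratio of technical replicate 2 over 1 (TMM) in 10 bins of transcript GC (left) and transcript length (right, log scale). Points are medians of each bin and bars the quartiles, and the medians run from -1.65 to 2.54 with GC and from 1.53 to -1.58 with length.

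The dominant transcript was the same in both libraries for 3024 of 5402 genes, or 56.0% (95% Clopper-Pearson interval 54.6 to 57.3). Where it differed, the one in replicate 2 was shorter for 1631 of 2378 genes. Among the 15 isoform genes fixed beforehand, 11 had the same dominant transcript. Ptprc, the leukocyte phosphatase CD45, was led by Ptprc-203 in replicate 1 (47.8%) and by the retained-intron transcript Ptprc-201 in replicate 2 (85.5%). Ighm was led by Ighm-201 (68.0%) and Ighm-202 (69.6%). Bcl2l1 and Fyn also differed, while Cd44 and Ikzf1 kept theirs.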

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

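The tests of another tissue, of GC content acting in both libraries, of few starting molecules, of a common factor, of depth at low counts, of GC and length as the whole cause, of erythroid cells, of the 2 alpha globin copies and of nuclear copies were chosen only after the result was seen. The design names no biological difference between the libraries. Rows with a numeric identifier, which no comparison uses, held 8 counts in technical replicate 2, above the limit of 3 that a count of 0 allows, and their identity was not analysed here.

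Between 2 libraries labelled as 1 spleen 7552 genes were called. Thinning replicate 1 to the total of replicate 2 (0 calls) decided nothing, since the rule already allows for counting error, nor did leaving out the globins (7548 calls), which moved the TMM scaling by only 0.0014 (log2). The median deviation of the log2 ratio in the most abundant of 10 bins by TPM was 134.3% of that over all tested genes. This percent cannot weigh depth at low counts, since the bins use the mean TPM of these same libraries. A gene far higher in either library can enter the top bin through its ratio, so no conclusion on depth is drawn. A common shift from abundant genes is argued against by 7296 calls among other genes under the best common factor. That factor was sought up to 4 log2 units either way. Of 36 B cell and red pulp macrophage genes, 35 reached 1 TPM in replicate 2, which argues against a tissue without these cells. Presence at 1 TPM cannot tell this spleen from another sample or tissue that holds them, or from a mixture. For few starting molecules, the residual SD in the most abundant of 10 bins was examined. It was 95.93% of that in the second least abundant bin and 80.1% of that in the least abundant. The count filter and the floor for a count of 0 limit ratios in low bins. In the second least abundant bin the median replicate 2 count was 12. The SD there may be understated, so no conclusion on starting molecules is drawn. The ratio followed GC (rho 0.5323) and length given GC (partial rho -0.3444), both weighted by transcript TPM in these same libraries. With both trends removed 6190 genes were called, 4168 of them in the direction called before, while 3197 of the 7552 calls were lost and 187 turned. These trends may account for part of the difference and not the whole. Whether GC acted within both libraries stayed open, with rho of ribosomal protein TPM with GC of -0.4038 in replicate 1 and 0.21 in replicate 2, short of the 0.3 set for it.

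The ratio of alpha to beta globin counts was 9.45 times higher in replicate 2. More erythroid cells would raise both together, so a change of this size argues against them as its cause, and reads shared between the 2 alpha copies are argued against by the log2 change of 3.24 in the ratio of their sum to beta globin. The GC trend of the other genes predicted 63.25% of the log2 difference (alpha 57.4% GC, beta 51.4%), so GC content is a candidate explanation for a large part of it. A change in erythroid content beside it was not excluded.

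Mitochondrially encoded genes had a median log2 ratio of -2.87, and -2.15 in their sum. Adding 6 nuclear copies took that sum to -2.38, a deeper fall. This argues against reads moving to those copies as the cause of the summed fall. It does not tell how reads were split between single genes and their copies, which was not tested. The GC trend of nuclear genes predicted 59.91% of the median. The median GC of the mitochondrial genes, 36.0%, lay below the lowest point of that trend, where the trend was held flat. The percent therefore rests on the trend's end value and is rough. GC content may account for part of the median. The rest, and the 5 members that were higher, had no tested explanation.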

How the results depend on the processing

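The removal of GC and length trends, the thinning of replicate 1, TPM without globins and the joint call under every scaling were chosen after seeing the data. Where values moved, the cause was not tested unless stated. Genes detected in both libraries were 4620 at 5 TPM, which is a stricter threshold. With 1 replicate left out no shared count exists, and the genes detected in the other numbered 9390 to 13937. Genes higher and lower were 1820 and 7295 under total counts, and 2295 and 2664 at a mean TPM of at least 10, where 7243 genes were tested. Under the joint call 1470 were higher. With GC and length trends removed they were 3267 and 2923, and 4168 genes were called in the same direction in both. The correlation was 0.733 with a pseudocount of 0.1, 0.539 among genes at 1 TPM in both, 0.789 over all genes and 0.734 as Spearman's rho. The technical coefficient of variation was 98.6% with no TPM filter, 96.1% at a mean TPM of 10, 94.99% with RLE factors and 108.2% without factors. The same dominant transcript was found for 53.5% of genes at 50 TPM and 58.1% where it held at least 60%. List medians above 0 numbered 14 of 26 under TMM, of which 10 fell below 0 under total counts and 13 as a TPM ratio, and the 12 below 0 stayed below under those 2. Total counts lower every ratio against TMM, so for that scaling this outcome was fixed in advance. Over genes with a mean TPM of 10 or more, 3 medians turned, NK and cytotoxic genes to 0.35, plasma cell genes to -0.64 and neutrophil genes to -0.09. With both trends removed 6 turned, 5 to below 0 and the sex check list to 0.31. As a TPM ratio, those that stood above their matched lists and turned were erythroid (-0.97), adipose and mesothelial (-0.36), cytosolic ribosomal protein (-0.033) and replication-dependent histone genes (-0.81). All of these lay above the median TPM ratio over tested genes, -2.10, so their turn reflects a lower zero point and not a place below the typical gene. No paired analysis was possible because there is 1 library on each side. The depth of replicate 2 limits calls of lower genes. At a fold of 0.5, 16 of 50 were found in the simulation, which used the TMM-scaled library sizes.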

Other observations

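Matching random lists also on GC content and length, chosen after seeing the data, moved several lists. Cytosolic ribosomal protein genes stayed high at percentile 99.95, adipose and mesothelial genes at 99.2 and histone genes at 98.8, and mitochondrially encoded genes stayed at 0. B cell genes went to percentile 0.30, immunoglobulin constant genes to 2.05 and pancreatic genes to 1.48. MHC class II genes went from 59.9 to 5.79, with a median of -1.28 once both trends were removed against 0.81 before. Immediate early genes went from 91.9 to 62.0, megakaryocyte and platelet genes from 85.9 to 34.5 and the sex check list from 13.6 to 70.8. Erythroid genes went from 97.8 to 95.5, inside the central 95% of random lists, and heme and iron handling genes from 95.3 to 85.0.

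Variable segments of both antigen receptor families were nearly absent from replicate 2. Scaled from replicate 1, immunoglobulin segments would have given 3688 counts where 3 were found, and T cell receptor segments 145.5 where 6 were found. Their cause was not tested.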
